A study of Homo sapiens and Mus musculus with 30 samples.

How the data were processed

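Single-cell RNA was measured with the 10x Chromium version 3 chemistry in 12 mouse lung tumour libraries and 18 human libraries (cultures and xenografts of NCI-H209 and NCI-H82). Tissue was dissociated with Miltenyi kits, per the labels' protocols. Each sample has a filtered matrix of deposited UMI counts per gene and cell, with 20612 human or 22583 mouse features. The matrices were made with Cell Ranger, per the submitters' processing notes, version 6.0.1 per the file headers. The builds were GRCh38 and GRCm39, per the submitters' processing notes. Coordinates are those of GENCODE release 29 on GRCh38, looked up by Ensembl ID for 66 genes, all 66 found, so the authors' annotation can differ in its ends. Values are whole numbers and were not normalized before deposit. The 4 matrices of the untreated H82 xenografts hold only even values, so each count was divided by 2. A pair of mouse libraries with identical values was counted once and left out of fits on age. The GFP feature was summed with the others, and no fold change of it is reported.

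Samples were grouped by title, and replicate numbers follow accession order, so they pair nothing. Cells with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept. Doublets were called with Scrublet, as run by scanpy, at a score above 0.25. This marked 682 mouse cells (1.60%), which were removed, and 1826 human cells (1.32%), which were kept. Before the mouse doublets were removed, 189 to 30558 human and 346 to 7224 mouse cells remained per library. Medians were 1849 to 42422 and 1788 to 10966 UMIs per cell. Human cells were sorted by line with 106 H82 and 212 H209 genes that differed at least 8-fold between the 2 cultures (at least 30 CPM, pseudocount 5), after 19 cells of the H209 culture with the H82 profile had been set aside. A cell with at least 10 such UMIs was H82-like above 70% H82 UMIs, H209-like below 30%, and between otherwise. This sorting was added after the data had been seen. Tumour-like cells of the human libraries are those outside clusters with markers of another cell type. These clusters came from Leiden resolution 0.3, 2000 variable genes, 20 principal components and 15 neighbours. Xenograft hosts are mice and only human genes were counted, so such clusters are not shown to be another cell type. Mouse cells were clustered at resolution 2 with 3000 variable genes and 40 components, which gave 53 clusters. A cluster was named from fixed markers when at least 3 were detected at 10 CPM with a mean log2 ratio of at least 1 and a lead of 1 over unrelated classes, thresholds set after seeing the data. A cluster also stayed unnamed when more markers of another class than of its own were among its 10 leading genes. A rule on low UMIs left no cluster unnamed. In all 12 clusters were unnamed. Of the markers 52 of 52 human and 208 of 209 mouse genes matched.

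Counts were summed per library over the cells of a class and tested with edgeR's quasi-likelihood test (TMM scaling, filterByExpr by group, robust), with Benjamini-Hochberg adjustment at 0.05. The 16 xenograft libraries shared 1 fit for treatment in each line, the interaction and the line difference. The comparison with culture had the line as a term. Mouse fits asked for 50 cells of the class per library, and fits on 1 kind of human cell for 10. CPM are printed on TMM-scaled library sizes except for H82-like and H209-like cells, where they are relative to the summed UMIs of those cells. MYC levels over all tumour-like cells printed beside those of H209-like cells are also relative to summed UMIs. Gene lists (27 per comparison) were tested with camera at a preset correlation of 0.01 and again with an estimated one. Of the list genes 888 of 899 human and 834 of 844 mouse symbols matched after older symbols had been looked up. Shares were compared with two-sided exact permutation tests, with Wilson intervals at 95% for single libraries.

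Named genes follow a rule: the 8 largest rises and 8 largest falls past the threshold with a mean of at least 10 CPM and no overlap between groups, up to 3 members of each list with the smallest p, and a set of subtype regulators, MYC family members, PAGE5 and GAGE2A. Clone-named, mitochondrial, ribosomal protein and haemoglobin genes were left out of the largest changes. Results for 1 gene that the rule names are not reported here. The design, lists, markers, naming rule and most alternatives were fixed before the data were examined. The alternatives fixed then were DESeq2, its size factors, no filter on low counts, 500 random cells per library and at least 2000 UMIs per cell. Others were all cells instead of tumour-like ones, at least 1% human mitochondrial UMIs, doublets treated the other way and libraries summed by title number. Other ages, other thinning, cancer testis antigen shares without PBK and ATAD2, and leaving out each library were also fixed then. Fits on cells of 1 line profile, shares with each unnamed mouse cluster under the class with its highest score, and fits on counts as deposited and on all cells with no mitochondrial limit were added after seeing the data. Each fit was tested on simulated counts with 100 genes changed by log2 1 and 100 by log2 2. At log2 1 it recovered 96% of them for treatment in H209, 96% for treatment in H82, 79% for the interaction, 93% for the line difference and 83% for culture.

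Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.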

Results

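Single-cell transcriptomes were measured with 10x Chromium version 3 chemistry in 30 libraries of small cell lung cancer, an aggressive neuroendocrine tumour of the lung. Of these, 12 came from mouse lung tumours and 18 from NCI-H209 and NCI-H82, established human lines of this cancer, grown in culture or as xenografts in mice. H209 is a classic line, and H82 is a variant line with an amplified MYC oncogene. The untreated mouse tumours were labelled 2 months (1 library), 3 months (1), 4 months (3), 5 months (3) and 6 months (2), and treated tumours 6 months (1) and 7 months (1). The human libraries were 1 culture of each line, 4 untreated and 3 treated H209 xenografts, and 4 untreated and 5 treated H82 xenografts. Treatment was cisplatin at 5 mg per kg, which crosslinks DNA, with etoposide at 10 mg per kg, a topoisomerase II poison that was repeated on the following 2 days. The series title places the question in chemoresistance and in cancer testis antigens, proteins of the germ line that many tumours re-express.

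The mouse libraries held 22385854 UMIs (unique molecular identifiers) at 2 months, 3088905 at 3 months, 22385854, 33807647 and 42008085 at 4 months, 12585636, 17991669 and 37398154 at 5 months, and 21892558 and 16715595 at 6 months. The treated ones held 73173358 (6 months) and 58958939 (7 months). The H209 culture held 21161049 UMIs, the untreated H209 xenografts 8746566, 76796125, 19648780 and 64483234, and the libraries labelled treated H209 xenograft 115232780, 111575776 and 104074479. The H82 culture held 57443043 UMIs, the untreated H82 xenografts 104765659, 139857837, 125499857 and 111383588, and the treated ones 109960052, 105064537, 50634731, 112914372 and 148432560. After filtering and before mouse doublets were removed, 137993 human and 42633 mouse cells remained. In the untreated H209 xenografts 1 and 3, where 38.6% and 43.3% of the UMIs of the median barcode were mitochondrial, 189 and 505 cells passed. The mouse libraries labelled 2 months and 4 months replicate 1 held identical values and were counted as 1 sample of unknown age. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these samples, which may be partly technical. The 4 untreated xenografts of each line share 2 numbers in their titles, and the 5 treated H82 xenografts share 4.

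The line of each human cell was read from genes that separate the 2 cultures. In the untreated H209 xenografts 90.3% ± 4.43 (SD, n = 4) of cells were H209-like, and 7.61% ± 3.95 were H82-like. The H209 culture itself held 13 H82-like cells of 607, or 2.14% (95% Wilson interval 1.26 to 3.63, which covers counting error only). In the 3 libraries labelled treated H209 xenograft, 92.7%, 92.6% and 94.8% of cells were H82-like (mean 93.4% ± 1.22, n = 3), and 166, 30 and 18 cells were H209-like, of which 134, 23 and 8 lay in tumour-like clusters and the others in clusters of other cell types, whose leading genes UBB and S100A6 also sort cells by line. Another 4.71%, 6.65% and 4.70% of their cells lay between both profiles. H82-like cells made up 99.7% of the H82 culture, 98.8% ± 0.395 of the untreated H82 xenografts (n = 4) and 95.6% ± 1.52 of the treated ones (n = 5). The data thus go against the label of the 3 treated H209 libraries for most of their cells, and every value below that draws on "the libraries labelled treated H209" compares a mixture of cells. The class rests on a share of line-specific UMIs and is a range, not a cell type.

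**Figure D1:**
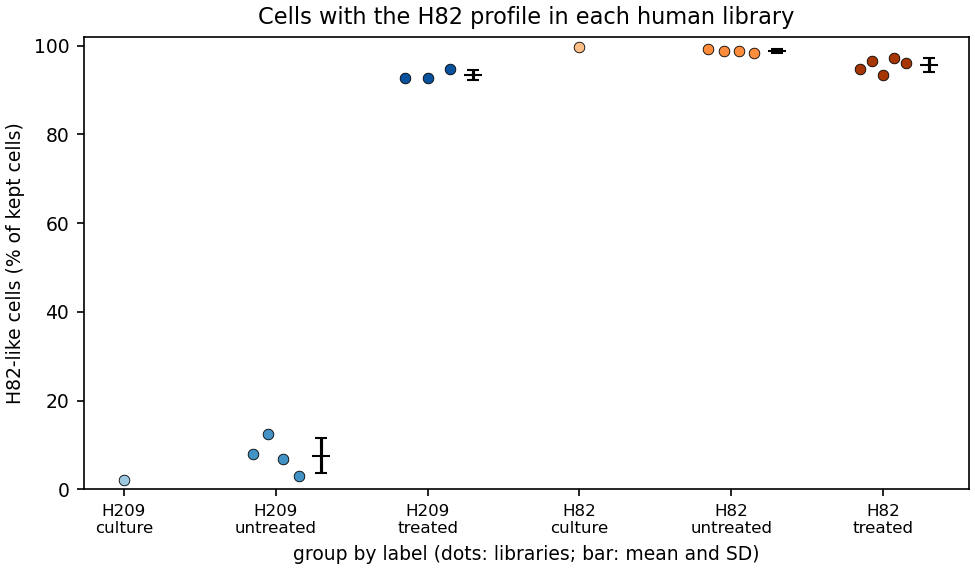
Share of kept cells with the H82 profile (%, vertical axis) in each human library (dots), by the group its label gives (horizontal axis), with the group mean and SD as bars. The 3 libraries labelled treated H209 xenograft lie at 92.6% to 94.8%, whereas the untreated H209 xenografts have a mean of 7.61%.

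Levels in the H82-like cells under the H209 label were set beside those in the H82 libraries. CYP1B1, an oestrogen- and xenobiotic-metabolising cytochrome P450 (ENSG00000138061, GRCh38 chromosome 2, 38066973 to 38109902), stood at 0.839 ± 0.408 CPM (UMI counts scaled to the library total) in H82-like cells of the libraries labelled treated H209 (n = 3) and 0.372 ± 0.433 in those of the untreated ones (n = 4). In H82-like cells of H82 xenografts it stood at 68.7 ± 27.2 when treated (n = 5) and 177 ± 15.9 when untreated (n = 4), and at 177 in the H82 culture. GAGE1, a cancer testis antigen on chromosome X (ENSG00000205777, 49589496 to 49608536), was at 6.73 ± 7.39 CPM under the H209 label when treated and at 0, 7.25, 79.6 (18 UMIs) and 0.342 in the 4 untreated libraries, against 283 ± 47.5 and 287 ± 31.6 in H82, whereas the H82-like cells of the H209 culture had 268 CPM. VCX, a testis gene on chromosome X (ENSG00000182583, 7842262 to 7844143), went the other way, with 293 ± 191 and 46.4 ± 39.6 CPM under the H209 label against 4.09 ± 0.895 and 1.28 ± 0.616 in H82. PAGE5, also a cancer testis antigen (ENSG00000158639, chromosome X, 55220355 to 55224108), was at 341 ± 87.3 CPM under the H209 label when treated, against 109 ± 33.3 in H82. Its untreated levels overlapped, at 69.1 to 122 CPM and 59.1 to 96.9. DUSP23, a dual-specificity phosphatase named after its values were seen, was at 0.0548 ± 0.0424 and 1.52 ± 1.98 CPM against 53.9 ± 8.05 and 67.5 ± 2.02. GAGE1 overlaps GAGE2A on the same strand, and GAGE, PAGE and VCX genes have near-identical copies, so counts within these families are uncertain. In the untreated H209 libraries 1 and 3, with 15 and 35 H82-like cells, 3 UMIs amount to 11.6 and 13.3 CPM, so low levels there are not resolved.

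**Figure D2:**
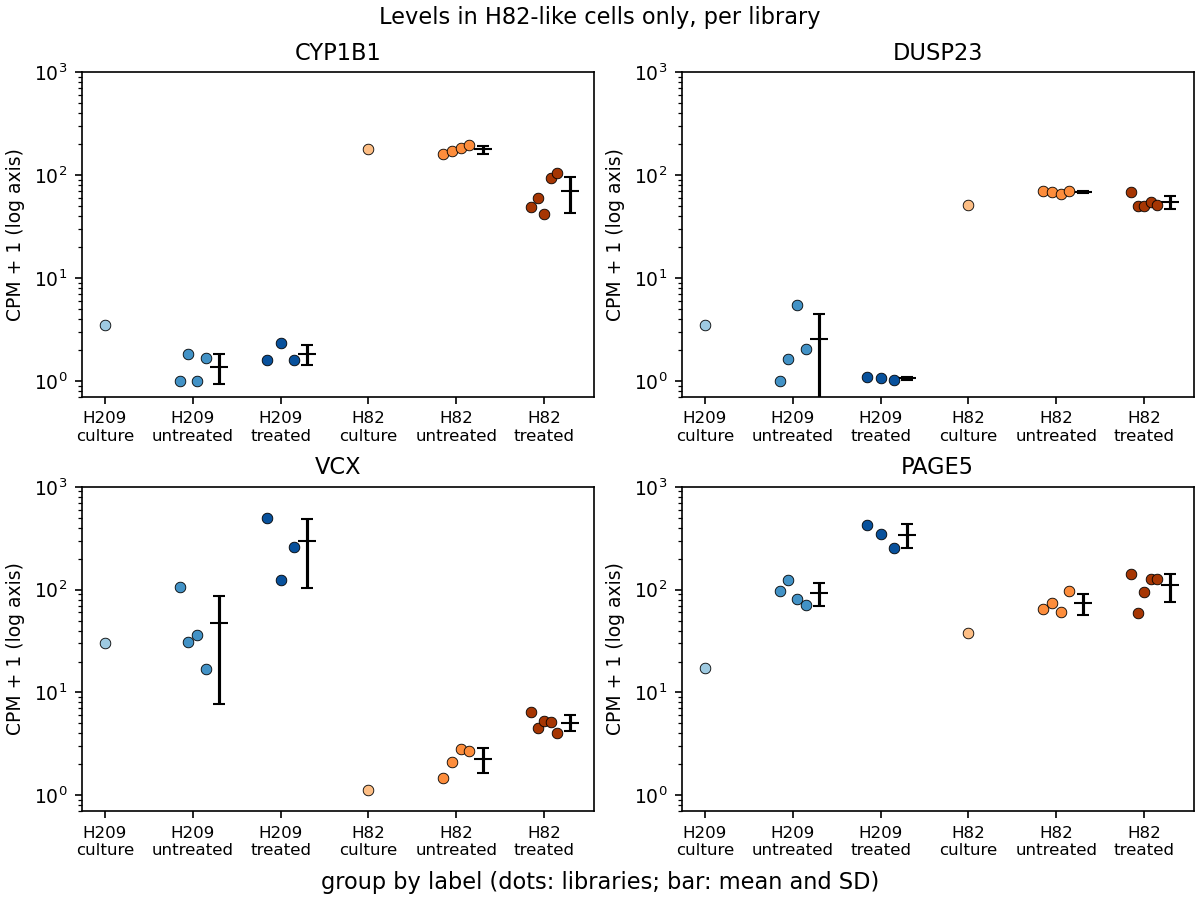
Levels of CYP1B1, DUSP23, VCX and PAGE5 in the H82-like cells of each human library (dots; CPM plus 1, log axis), by label group. CYP1B1 and DUSP23 lie near 0 under the H209 label and at 50.6 or more CPM in each H82 group mean, whereas VCX is higher under the H209 label.

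Untreated xenografts of the 2 lines differed in neuroendocrine regulators and in MYC. INSM1, a zinc-finger factor of neuroendocrine cells (ENSG00000173404, chromosome 20, 20368121 to 20370949), was lower in H82 (log2 change −4.54 ± 0.20 SE, adjusted p = 4.06e-12; 16.7 CPM in H82 against 391 in H209, n = 4 each), and so was MYCL (−2.68 ± 0.17). MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434) was higher in H82 by 3.79 ± 0.30 (adjusted p = 9.33e-09; 1018 ± 125 against 73.4 ± 29.3 CPM), and NEUROD1, a neurogenic transcription factor, by 1.80 ± 0.30. Of 36 neuroendocrine genes 8 were higher and 22 lower in H82, the same counts when adjusted over the list alone, with median −0.62 and mean −3.08 (camera adjusted p = 0.00815, adjusted p = 0.752 with an estimated correlation). Epithelial genes went lower in 17 of 18, including KRT7 (keratin 7, −7.84 ± 0.61), with 1 higher (adjusted over the list alone also 17 and 1; adjusted p = 3.95e-05, 0.752 with an estimated correlation as adjusted p). TFF3, a trefoil factor secreted by mucous epithelium, stood at 0.0450 ± 0.0251 CPM in H82 and 787 ± 166 in H209.

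Ribosome-related groups were higher in untreated H82. Ribosomal protein genes were higher in 75 of 77 and lower in 0 (median log2 1.31), and ribosome biogenesis genes higher in 32 of 36 and lower in 1 (median 1.49). Immediate early genes, which report acute signalling and also dissociation stress, were lower in 27 of 30, among them EGR1 (−8.07 ± 0.30; 0.459 against 126 CPM), and higher in 2. Counts adjusted over the list alone were the same for these 3 lists. Their camera adjusted p were 1.54e-13, 2.51e-11 and 7.6e-08, and none held with an estimated correlation, where the lowest adjusted p of any list was 0.752. Of 70 cancer testis antigens 37 were higher in H82 and 14 lower, and the list did not pass (adjusted p = 0.062). GAGE2A was higher by 3.803 ± 0.40 (1062 against 74.97 CPM) and PAGE5 by 3.16 ± 0.54, or by 4.48 and 4.50 without the untreated H209 library 2. In all, 12176 of 16155 genes differed (6197 higher and 5979 lower in H82, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The matrices of untreated H82 held only even values and those of untreated H209 did not, so this property coincides with the line. Between H82-like cells under both labels 3572 genes differed, with MYC at −0.14, PAGE5 at −0.20 and NEUROD1 at −0.42. The untreated H209 libraries held 2.98% to 12.6% H82-like cells, which are part of the levels above. With cells of the labelled line's profile alone the line difference was 8.46 for MYC, 8.05 for GAGE2A and 7.51 for PAGE5, where MYC and GAGE2A are among the genes that sorted the cells and PAGE5 is not.

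Libraries labelled treated H209 were compared with untreated H209 xenografts to see what followed chemotherapy. Over all tumour-like cells, MYC was higher by 3.58 ± 0.31 (adjusted p = 4.37e-08; 885 ± 147 CPM, n = 3, against 73.4 ± 29.3, n = 4) and NEUROD1 by 2.19 ± 0.31. INSM1 was lower by −3.60 ± 0.22 (adjusted p = 4.87e-10; 32.3 against 391 CPM), MYCL by −2.77 ± 0.19, and GRP, the gastrin-releasing peptide of neuroendocrine cells, by −8.19 ± 0.48 (0.137 against 40.2 CPM). Of 70 cancer testis antigens 51 were higher and 7 lower, the same when adjusted over the list alone (median log2 3.45, adjusted p = 2.42e-05, adjusted p = 0.582 with an estimated correlation). PAGE5 was higher by 5.27 ± 0.60 (379 ± 86.4 against 8.83 ± 9.19 CPM), GAGE2A by 3.76 ± 0.41 and VCX by 6.25 ± 0.55. Without the untreated H209 library 2 the values were 6.62 for PAGE5 and 4.43 for GAGE2A. H82-like cells made up 93.4% of the libraries on 1 side of this comparison and 7.61% on the other, and 11512 genes differed (5982 higher, 5530 lower, edgeR).

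Within cells of 1 profile fewer genes differed, from fewer cells (15, 376, 35 and 94 untreated H82-like cells, and the 166, 30 and 18 treated H209-like ones). Among H82-like cells 873 genes differed between the libraries labelled treated and untreated H209 (443 higher, 430 lower), of which 715 had also passed over all cells, 568 in the same direction and the others in the opposite one. MYC (−0.26), MYCL (0.12), NEUROD1 (0.00), GAGE2A (0.16) and INSM1 (−0.54) did not pass there, whereas PAGE5 (1.99 ± 0.34, adjusted p = 0.0035) and VCX (3.41 ± 0.61, adjusted p = 0.0072) were higher in the treated libraries. Of 65 cancer testis antigens 4 were higher and 0 lower. Among H209-like cells 1003 genes differed (567 higher, 436 lower). There MYC was higher by 4.19 ± 0.48 (adjusted p = 6.84e-05) and PAGE5 by 5.79 ± 0.66 (adjusted p = 1.68e-04). NEUROD1, which was higher over all tumour-like cells, had a negative log2 change in this fit. Restricted to tumour-like clusters, without the library that kept 8 cells, 708 genes differed, with MYC at 3.71 ± 0.45 and PAGE5 at 5.72 ± 0.71. Those H209-like cells lay among H82-like RNA. MYC stood at 51.3, 70.2 and 173 CPM in them beside 656, 816 and 873 over all tumour-like cells of the same libraries. It stood at 1.66 to 5.52 in untreated H209-like cells, and all these values are relative to summed UMIs.

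Other groups differed as well over all tumour-like cells. Epithelial genes were lower in 17 of 18 and higher in 1 (CLDN3, a tight-junction claudin, −4.47 ± 0.31; adjusted p = 2.14e-05, adjusted p = 0.603 with an estimated correlation). Immediate early genes were lower in 23 of 30 and higher in 1 (EGR1 −7.17 ± 0.33; adjusted p = 1.65e-07, adjusted p = 0.582 with an estimated correlation). Ribosomal protein genes were higher in 74 of 77 and lower in 0 (RPL11 2.47 ± 0.20; adjusted p = 5.1e-17, adjusted p = 0.65 with an estimated correlation). Cholesterol synthesis genes were lower in 18 of 25 and higher in 1 (adjusted p = 0.0076, adjusted p = 0.715 with an estimated correlation). Each count was the same when adjusted over the list alone. BCL2, the anti-apoptotic regulator, was lower by −3.80 ± 0.23. Within H82-like cells, 7 of 17 epithelial genes were lower and 0 higher, 13 of 29 immediate early genes lower and 0 higher, 14 of 77 ribosomal protein genes higher and 0 lower, and 1 of 24 cholesterol synthesis genes lower and 0 higher.

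Treated H82 xenografts, whose cells were H82-like in both groups, had higher interferon response and leukocyte genes than untreated ones, and lower cholesterol synthesis, amino acid response and ribosome biogenesis genes. With an estimated correlation none of these lists passed, and the lowest adjusted p of any list was 0.309. MYL4, an embryonic and atrial myosin light chain (ENSG00000198336, chromosome 17, 47200446 to 47223679), rose by 2.89 ± 0.18 (adjusted p = 1.11e-07; 55.7 ± 10.6 CPM, n = 5, against 7.51 ± 0.753, n = 4). TNNC2, a fast-muscle troponin, rose by 2.30 ± 0.32 and NEB, nebulin of the sarcomere, by 2.35 ± 0.30. Of 32 interferon response genes 17 rose and 1 fell (18 and 1 adjusted over the list alone), including IFI6 (3.07 ± 0.61, adjusted p = 0.00149), ISG20 (2.06 ± 0.27) and USP18 (1.45 ± 0.27). The list had an adjusted p of 0.000307, and an adjusted p = 0.4656 with an estimated correlation. IFI6 stood at 41.1 CPM in the treated library 3 and at 4.06 and 4.67 in libraries 4 and 5, and its log2 change was 2.27 without library 3. MYCN rose by 1.69 ± 0.23 from a low level (11.9 ± 1.23 against 3.67 ± 0.382 CPM), as did TP53INP1, a p53-induced stress gene (2.66 ± 0.31).

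Among genes that fell were linker histones, with H1-5 (ENSG00000184357, chromosome 6, 27866849 to 27867529) at −2.31 ± 0.24 (adjusted p = 1.37e-05; 15.02 ± 6.34 against 74.4 ± 6.10 CPM) and H1-4 at −2.18 ± 0.21. Of 28 histone genes 13 fell and 5 rose (13 and 6 adjusted over the list alone; adjusted p = 0.00211, adjusted p = 0.409 with an estimated correlation). Cholesterol synthesis genes fell in 20 of 25 and rose in 1, with the same counts adjusted over the list alone, among them SQLE, squalene epoxidase (−1.18 ± 0.17). The list had adjusted p = 3.02e-06, and adjusted p = 0.409 with an estimated correlation. Of 33 unfolded protein and amino acid response genes 20 fell and 1 rose (21 and 1 adjusted over the list alone), with ASNS, asparagine synthetase, at −1.54 ± 0.15 and PHGDH, of serine synthesis, at −1.13 ± 0.11 (adjusted p = 5.6e-06, adjusted p = 0.309 with an estimated correlation). Ribosome biogenesis genes fell in 28 of 36 (30 adjusted over the list alone), including NCL, nucleolin (−1.10 ± 0.12), and ribosomal protein genes in 55 of 77 (58 adjusted over the list alone), with 0 rising in both lists. Their adjusted p were 1.61e-12 and 4.62e-11, and adjusted p = 0.359 and 0.454 with an estimated correlation. Of 46 DNA repair genes 25 fell and 0 rose, the same adjusted over the list alone (median −0.24, adjusted p = 2.24e-05, adjusted p = 0.323 with an estimated correlation), with BARD1, the partner of BRCA1, at −0.57.

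**Figure D3:**
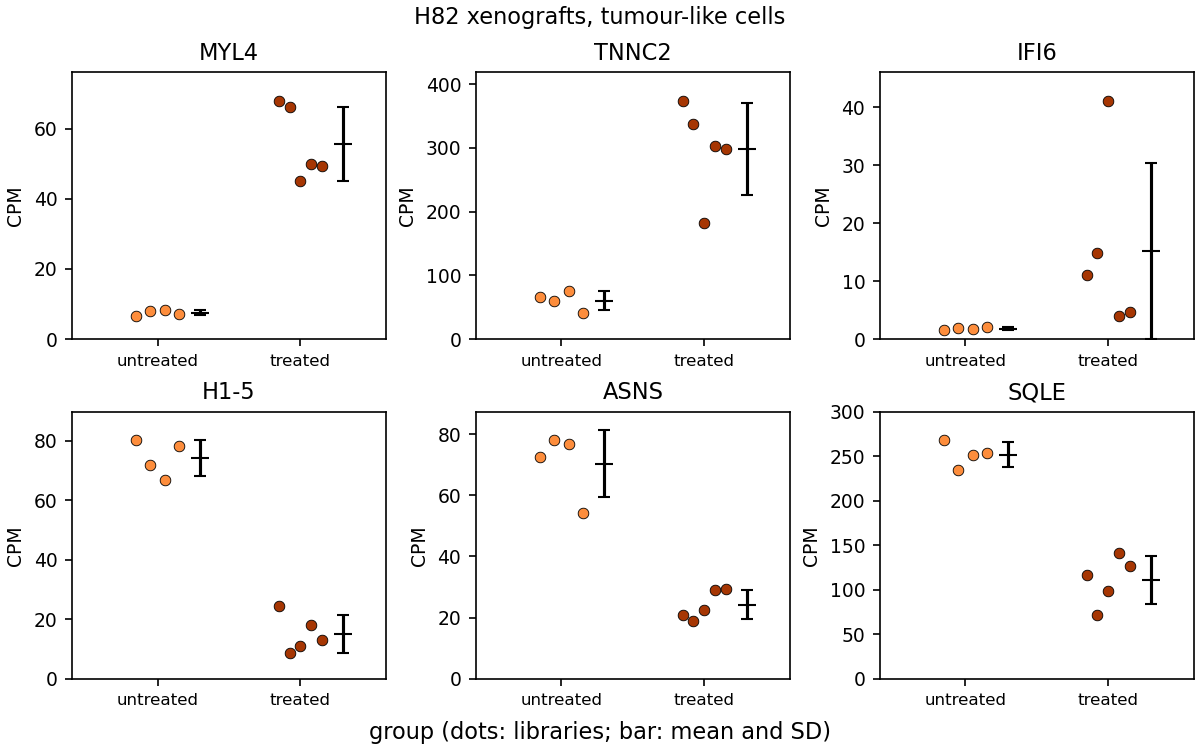
Levels (CPM, vertical axes) of MYL4, TNNC2, IFI6, H1-5, ASNS and SQLE in tumour-like cells of the untreated (4) and treated (5) H82 xenografts, a dot per library with the mean and SD as bars. MYL4 has means of 7.51 untreated and 55.7 treated, whereas H1-5 has 74.4 and 15.02.

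Most subtype regulators and cancer testis antigens did not pass in H82. MYC (0.16 ± 0.26, adjusted p = 0.650), NEUROD1 (0.19, adjusted p = 0.610), PAGE5 (0.25 ± 0.46, adjusted p = 0.683) and GAGE2A (−0.51 ± 0.34, adjusted p = 0.237) did not pass. Of 70 cancer testis antigens 11 rose and 2 fell (6 and 0 adjusted over the list alone), and the list did not pass (adjusted p = 0.402). CYP1B1 fell by −1.69 ± 0.29. Markers of other cell types moved with treatment: 8 of 13 leukocyte genes and 5 of 12 fibroblast and endothelial genes rose (9 and 5 adjusted over the list alone) and 0 fell, with CD68 at 4.04 against 1.02 CPM and COL1A2 at 2.91 against 0.457. Their adjusted p were 0.000912 and 0.00243, and adjusted p = 0.316 and 0.309 with an estimated correlation. Host cells of a xenograft are of the mouse, and only human genes were counted. Whether these UMIs, or those of the muscle genes MYL4, TNNC2 and NEB, come from tumour cells or from mouse RNA assigned to human genes was not tested. In all 6725 of 16155 genes differed (3706 higher, 3019 lower, edgeR), 2568 with 500 cells per library and 4274 with libraries summed by title number. The 4 untreated H82 matrices held only even values and were halved, a property that coincides with the untreated group.

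The treatment effects of both lines were set against each other as an interaction, with the reservation on labels above. The effect in H82 minus that in H209 differed from 0 for 10714 genes (5288 above 0, 5426 below). It was −3.43 ± 0.39 for MYC, 2.44 ± 0.24 for MYCL, −5.02 ± 0.73 for PAGE5 and −4.27 ± 0.52 for GAGE2A. Without the untreated H209 library 2 it was −6.36 for PAGE5 and −4.95 for GAGE2A. Of 70 cancer testis antigens 40 were below 0 and 5 above (39 and 5 adjusted over the list alone; adjusted p = 0.00107, adjusted p = 0.485 with an estimated correlation). Within H82-like cells the count was 1942 genes, with 0 cancer testis antigens above 0 and 4 below. Across 16155 genes, which are not independent replicates, the 2 effects had Pearson's r = −0.139 and Spearman's rho = −0.165. Within H82-like cells r was 0.372 and rho 0.223 over 15280 genes, but r was −0.0556 and rho −0.0955 over 3925 genes with at least 20 CPM that were under 2-fold apart between the cultures (exact permutation p = 0.676 for r). The value of 0.372 was not set against regroupings.

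The share of cells with at least 1 cancer testis antigen UMI was compared after each cell had been thinned to 2000 UMIs. It was 99.7% ± 0.0741 in the libraries labelled treated H209 (n = 3) and 85.3% ± 1.55 in untreated ones (n = 4), a difference of 14.4 points (two-sided exact permutation p = 0.0286, the smallest that 35 splits allow). Without thinning the shares were 99.8% ± 0.114 and 94.2% ± 4.92 (exact p = 0.171). Without PBK and ATAD2, members of the list, they were 99.7% ± 0.0659 and 76.1% ± 1.83 at 2000 UMIs (exact p = 0.0286). Among H82-like cells alone the shares were 99.9% ± 0.0770 and 100% (difference −0.122, n = 3 each, exact p = 0.1), and among H209-like cells 81.1% ± 17.2 (n = 3) and 83.5% ± 0.398 (n = 4; exact p = 0.886). Of the latter, those in tumour-like clusters had 90.2% ± 6.38 (n = 2) and 83.9% ± 1.14 (n = 4; exact p = 0.0667, the smallest that 15 splits allow). In H82 xenografts the share was 99.6% ± 0.199 treated (n = 5) and 99.7% ± 0.0729 untreated (n = 4, exact permutation p = 0.222). Unthinned it was 99.6% and 99.7%. Untreated shares near 100% in H82 and in H82-like cells leave no room for a rise, so these comparisons cannot show one. Thinning left out 58, 131, 151 and 255 cells of the untreated H209 xenografts and 1610, 1498 and 355 of those labelled treated. Among cells outside tumour-like clusters of the treated library 1, 27 of 29 showed such a UMI (93.1%, median 2262 UMIs before thinning). This stood beside 99.8% of tumour-like cells (median 18658), so the share there does not count expressing cells. The untreated H209 libraries offer no such background, since the 29 cells of library 1 outside tumour-like clusters all had the H209 profile.

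**Figure D4:**
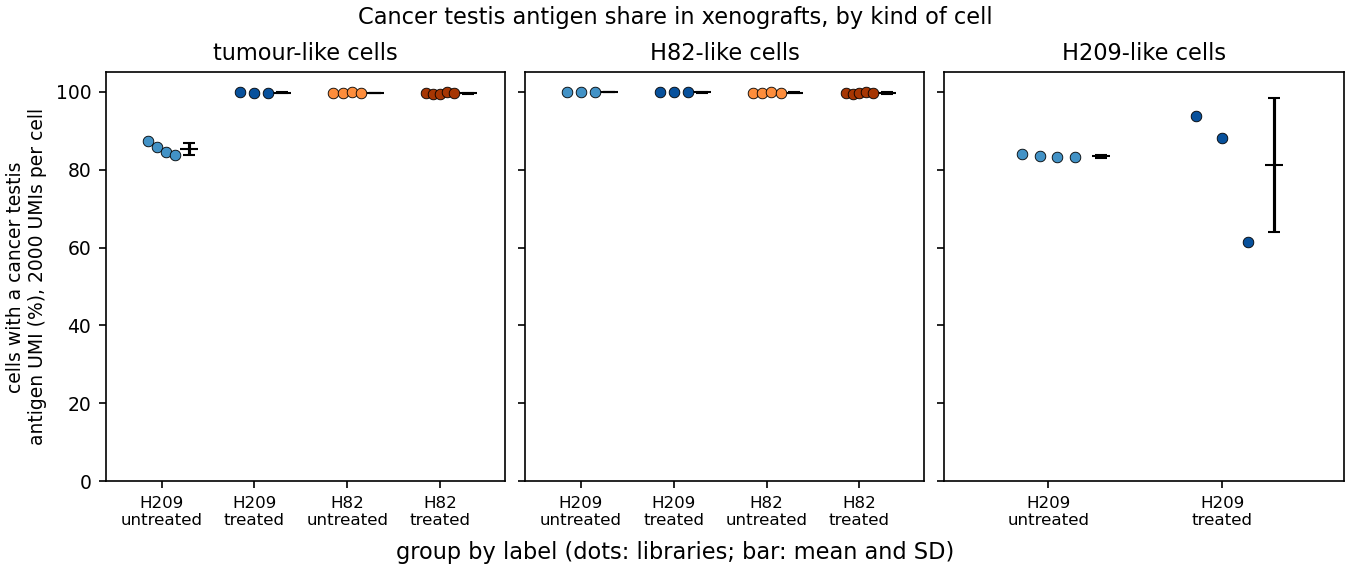
Share of cells (%, vertical axis) with at least 1 cancer testis antigen UMI at 2000 UMIs per cell, in tumour-like, H82-like and H209-like cells of each xenograft library with at least 10 such cells (dots), by label group with mean and SD. Untreated H209 xenografts have a mean of 85.3% over tumour-like cells and 83.5% over H209-like cells.

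Untreated xenografts were compared with the culture of their line, 1 culture each, to see what growth in the animal changed. MS4A15, a lung-expressed membrane protein, was higher in xenografts (6.07 ± 0.34, adjusted p = 1.29e-05), almost wholly through H209 (37.9 against 0.556 CPM). DLK1, a non-canonical Notch ligand, was higher in both lines (4.05 ± 0.42, adjusted p = 0.00113; 43.5 ± 13.1 against 3.89 CPM in H209, n = 4 against 1, and 10.6 ± 2.04 against 0.277 in H82, n = 4 against 1), as was CDH2, N-cadherin (1.73 ± 0.23, adjusted p = 0.00321). WFDC1, a secreted protease inhibitor of the WAP family, was lower (−2.37 ± 0.26, adjusted p = 0.00151; 4.01 against 24.2 CPM and 44.7 against 236). ID3, a helix-loop-helix inhibitor induced by BMP, was lower (−5.62 ± 1.16) mainly in H82 (1.52 against 207 CPM, and 45.0 against 57.5 in H209). Of 30 immediate early genes 7 were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.00282, adjusted p = 0.816 with an estimated correlation). Of 33 unfolded protein and amino acid response genes 1 was higher and 5 lower (2 and 13 adjusted over the list alone; adjusted p = 0.0126, adjusted p = 0.816 with an estimated correlation).

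In total 1074 of 15529 genes differed between xenografts and cultures (462 higher and 612 lower in xenografts, edgeR). MYC (0.78, adjusted p = 0.124) and PAGE5 (1.42, adjusted p = 0.201) did not pass. Of 56 cancer testis antigens 1 was higher and 0 lower (0 and 0 adjusted over the list alone). Below, fits within 1 line or without a culture set xenografts against a single culture library. Their counts cannot separate growth in the animal from that library. Within H82 the xenograft matrices held only even values and the culture did not, so this property coincides with growth in the animal there. In H209 neither side held only even values. The count was 3311 without the H209 culture, 1915 without the H82 culture, 453, 482, 623 and 619 without the untreated H82 xenografts 1, 2, 3 and 4, 464 within H209 alone and 6012 within H82 alone. MS4A15 did not pass without the H209 culture (4.42), where DLK1 was 5.25, nor did ID3 without the H82 culture (−0.30).

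Mouse lung tumours were compared by treatment and by age. Tumour-like cells, which carry neuroendocrine markers, differed in 0 genes between treated tumours (n = 2) and untreated tumours of 5 and 6 months (n = 5) by edgeR and 0 by DESeq2. By edgeR 110 genes had an unadjusted p under 0.05, which is fewer than the share of 0.05 of the tested genes that chance would give (11837 genes were tested in simulated data for this comparison). The log2 change was 0.18 ± 0.36 for Myc, with Mycl at −0.18 ± 0.44 and Mycn at −0.58 ± 0.79 (adjusted p = 0.99997 each). In simulated data for this comparison 20 of 100 genes changed by log2 1 and 85 of 100 changed by log2 2 were recovered. Most cells of the class came from cluster 5 in the treated tumours (615 of 1155 and 226 of 384 cells) and in the untreated libraries 5 months replicate 3 (98 of 149) and 6 months replicate 1 (167 of 308). Other clusters led elsewhere, with 38 (382 cells) in 5 months replicate 1, 30 and 29 (415 and 319 cells) in 5 months replicate 2, and 39 and 20 (78 and 59 cells) in 6 months replicate 2. Cluster 39 had Lyz2 at 8104 CPM, against 211 in cluster 5 and 30120 in the macrophage-like cluster 3. Whether such RNA in cells of this class altered the fit was not tested. By list, histone genes had a median of −1.30 (adjusted p = 2.86e-16), G2/M genes −0.29 (adjusted p = 4.04e-09) and interferon response genes 0.28 (adjusted p = 5.19e-07), each at an adjusted p = 0.742 with an estimated correlation and with 0 members higher and 0 lower, also adjusted over the list alone.

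Across untreated mouse tumours of 3 to 6 months (n = 8) 0 genes changed per month in tumour-like cells by edgeR, 58 by DESeq2 and 735 at an unadjusted p under 0.05. Myc moved by 0.03 ± 0.20 per month (adjusted p = 0.999) and Mycl by 0.42 ± 0.17 (adjusted p = 0.705). The lists of G2/M genes (median 0.48 per month; 35 of 54 higher and 0 lower adjusted over the list alone, 0 over all genes) and of hypoxia genes (0.38; 15 of 34 and 0) passed with adjusted p = 3.4e-49 and 3.99e-18, and had adjusted p = 0.197 with an estimated correlation. The clusters within the class differed by library, and cluster 20, led by cell cycle genes, held 3 of 57 cells at 3 months, 29 of 1002 and 0 of 51 at 4 months, 97 of 647, 153 of 1053 and 10 of 149 at 5 months, and 37 of 308 and 59 of 170 at 6 months. Cluster 35 held 311 of the 1002 cells of 4 months replicate 2. Before doublets were removed, 34.75% of cluster 35 were called doublets and its Lyz2 level was 13710 CPM. In macrophage-like or monocyte-like cells (treated n = 2, untreated n = 4) 1 gene differed: Krt79 (ENSMUSG00000061397), a keratin gene used here as a marker of alveolar macrophages, was lower by −2.23 ± 0.26 (adjusted p = 0.0263; 10.5 ± 2.14 against 47.4 ± 12.6 CPM). DESeq2 gave 4 genes and 500 cells per library gave 0. Without the untreated libraries 5 months replicate 3, 6 months replicate 1 or 6 months replicate 2 the count was 0, and without the treated library of 6 months it was 6. This class came mostly from cluster 3 in the treated tumours (663 and 479 cells) and from cluster 44 in 5 months replicate 1 (2057 cells).

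No cell class passed the adjusted test for treatment or for month. Tumour-like cells made up 11.8% ± 6.34 of treated tumours (n = 2) and 21.1% ± 28.8 of untreated tumours of 5 and 6 months (n = 5, exact permutation p = 0.857). The difference ranged from −13.85 to 3.37 points when single libraries were left out. Alveolar macrophage-like cells made up 29.4% ± 6.51 and 19.4% ± 19.8, and T cell-like cells 10.6% ± 13.5 and 6.495% ± 12.3. The T cell-like share was 1.10% and 20.1% in the treated tumours and 0.0192% to 28.3% in the untreated ones. In the treated library of 7 months 497, 93 and 54 such cells lay in clusters 47, 51 and 52, with Rag1 or Dntt among their leading genes. At least 94.8% of each of these clusters came from that library. Neutrophil-like cells made up 1.47% and 1.73% of the treated tumours and 0% to 1.30% of the untreated ones (two-sided exact p = 0.0476, the smallest that 21 splits allow, and 0.476 after adjustment over 10 classes). Over 8 untreated libraries their share had Pearson's r = −0.741 with month (permutation p = 0.0244, adjusted over 10 relations 0.244) and Spearman's rho = −0.531 (p = 0.188). Without the library of 3 months and 1 of the 4 libraries of 4 or 6 months, the farthest from the median month, r ranged from −0.575 to −0.160. Clusters left unnamed held 26.6% ± 15.8 of treated and 35.7% ± 33.9 of untreated cells, and 93.8% of 6 months untreated replicate 2. Of these, cluster 10 had alveolar macrophage markers at a mean log2 ratio of 2.03 but was led by other genes, such as Ereg, S100a4 and Il1b. It held 1830 of the 7094 cells of the treated library of 6 months, which the alveolar macrophage-like share leaves out. Cluster 21, which also scored highest for that class, held 1585 of the 5216 cells of 5 months replicate 1, and cluster 50, which scored highest for the tumour-like class, held 3541 of the 5418 cells of 6 months untreated replicate 2. With unnamed clusters counted under the class with the highest score, a count chosen after seeing the data, tumour-like cells made up 13.5% ± 8.16 of treated and 43.1% ± 42.8 of untreated tumours (exact permutation p = 0.476), alveolar macrophage-like cells 48.0% ± 12.03 and 29.7% ± 24.2 (exact p = 0.429), and no class passed.

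**Figure D5:**
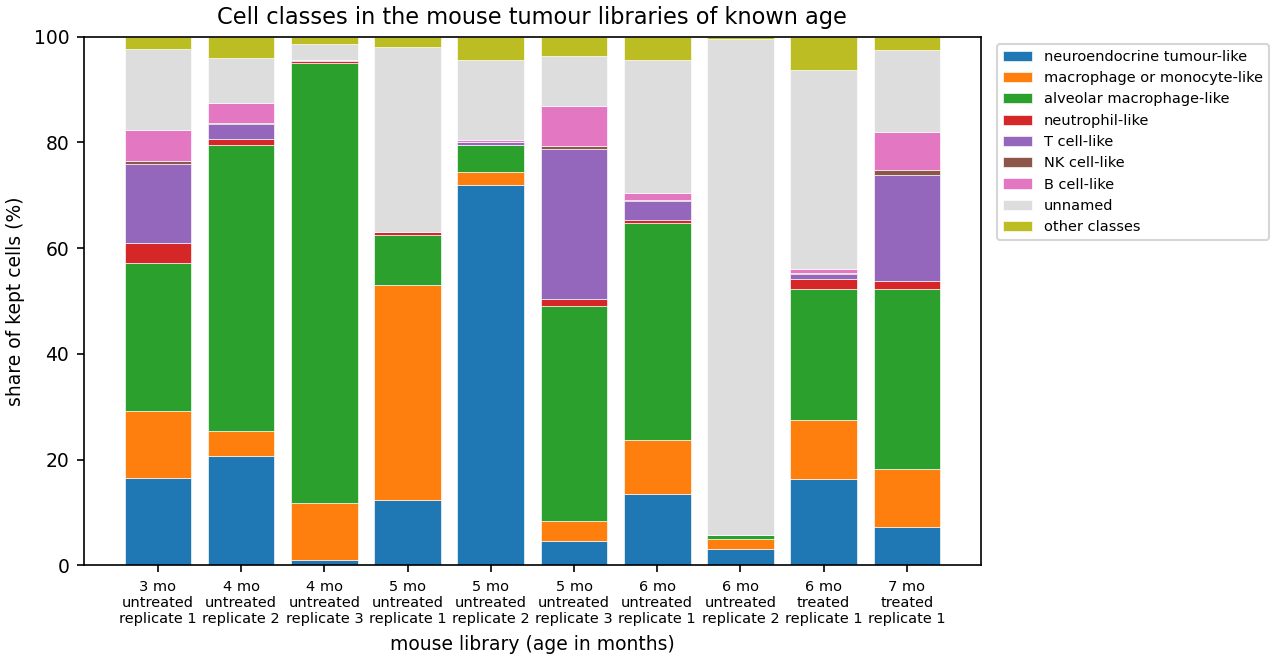
Share of kept cells (%, stacked bars from 0 to 100) by cell class in the 10 mouse libraries of known age, with the identical pair left out. Unnamed clusters hold 93.8% of the second untreated library of 6 months, and neuroendocrine tumour-like cells 72.0% of the second untreated library of 5 months.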

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

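The tests on exchanged labels, on a state that appears with treatment, on H82-like cells of a separate kind, the windows per treated library and with tumour-like clusters alone, the count of unnamed mouse clusters and the fits on counts as deposited were chosen after the result was seen, and the remaining tests here were set beforehand.

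The 3 libraries labelled treated H209 xenograft held 93.4% ± 1.22 H82-like cells, against 7.61% ± 3.95 in 4 untreated ones. An exchange with treated H82 libraries would leave H209-like cells there, and the highest share found was 0.535%; a state that appears only with treatment is argued against by H82-like cells in all 5 untreated libraries labelled H209, at least 2.14% each, and a state that keeps the chromosome dosage of H209 by r = 0.834 with the culture difference over 69 windows of 100 genes in the library with 166 H209-like cells, also 0.834 with the 134 of them in tumour-like clusters. Set against untreated H209-like cells, all 3 libraries gave 0.847 to 0.874 in these windows, and 0.651 to 0.660 over genes under 2-fold apart between the cultures, although windows also carry genes regulated together. Cells of the H82 line stay open: 85.0% of 3349 genes not used for sorting lay nearer the H82 culture, short of the 90% set beforehand. Treated H82 libraries (86.7%) missed this bound as well, so it cannot decide. The share was 92.2% in untreated H82 libraries and 6.87% in H209-like cells of the untreated libraries labelled H209. H82-like cells of a kind seen in no H82 xenograft here are a candidate explanation, since 80.8% of 26 genes at least 4-fold apart in treated libraries were 2-fold apart in untreated ones (21 genes, just past a bound of 80%, although GAGE1, one of them, was as high in H82-like cells of the H209 culture, at 268 CPM, as in H82), while their presence in the H209 stock before treatment cannot be told apart from a later entry (r = 0.329 across 3925 genes), and an effect of treatment on the proportions of both kinds stays open as untested.

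The genes that differed between treated and untreated H82 xenografts coincide with matrices that hold only even values. Reads from introns in 1 group are argued against by rho = −0.0688 between fold change and intron length over 6715 genes. Depth per cell stays open, since 6671 genes with at least 2000 UMIs per cell, against 6725, come from a limit that does not match depth between the groups (medians of 1849 to 5483 UMIs untreated and 2497 to 11834.5 treated). Counts as deposited gave 6927 genes, which decides nothing, since scaling removes a factor common to all genes of a library. A separate processing run or batch of the untreated libraries cannot be excluded, since it coincides with treatment, and the effect of treatment stays open beside it. The line difference, the interaction and the H82 side of the culture comparison use the same untreated libraries, and these tests did not cover them.

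Over splits of libraries, taken as independent, chance can be excluded for 4 counts of genes, where 1 split, the real one, gave as many. These are treatment in the libraries labelled H209 (11512, highest other of 35 splits 7897), treatment in H82 (6725, highest other of 100 splits 4686), the interaction (10714, highest other of 100 splits 9160) and the line difference (12176, highest other of 35 splits 0). In all but treatment in H82, the real split also separates mostly H82-like from mostly H209-like cells, so those counts cannot be assigned to treatment. Were libraries with a shared title number 1 animal, there would be 10 splits for treatment in H209 and 15 for treatment in H82. With 3 for the line difference, these are too few for a share under 0.05, and chance would not be excluded. Chance cannot be excluded for the correlation of both treatment effects, r = −0.139, as 11 of 100 regroupings lay as far from 0 and the others reached 0.219.

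The treatment effect in H82 minus that in H209 differed from 0 by its own test (edgeR) for 10714 genes. Among them were NEUROD1 (−2.0006 ± 0.41), POU2F3 (5.01 ± 1.24, adjusted p = 0.00173) and MYC (−3.43 ± 0.39). MYCN (−1.33 ± 0.37) was also among them, at −2.25 without the untreated H209 library 2. So were MYCL (2.44 ± 0.24), PAGE5 (−5.02 ± 0.73) and GAGE2A (−4.27 ± 0.52). The H209 side compares mostly H82-like with mostly H209-like cells. With H82-like cells in every library NEUROD1, MYC, MYCN and MYCL had the opposite sign. Among untreated mouse tumours of 5 and 6 months, replicate 3 of 5 months stood apart with 28.3% T cell-like, 7.44% B cell-like, 1.39% plasma cell-like and 0.682% NK cell-like cells, where the highest of the others had 3.52%, 1.45%, 0% and 0.176%. In 5 months replicate 1 macrophage-like or monocyte-like cells made up 40.6% (others at most 10.2%). Of these 2057 lay in cluster 44, whose mean log2 ratio was 1.72 for this class and 1.38 for alveolar macrophages. No lead between these classes was asked for. In 5 months replicate 2 tumour-like cells made up 72.0% (others at most 13.5%). With unnamed clusters counted under the class with the highest marker score, it had 83.0% and 6 months replicate 2 had 96.0%, so it does not stand apart by that count. YAP1 stood at 0.0970 CPM in the treated H82 xenograft 3 (others at most 0.0132), and MYCN at 1.87 CPM in the untreated H209 xenograft 2 (others at most 0.602). Of 56 groups and measures looked at 8 stood apart in this way, where chance gives about 1 in 20 by Dixon's 95% limit for independent normal values. Shares within a library, 4 of these 8, are not independent. The GFP feature, for which no comparison is reported, had 526 UMIs in the untreated H82 xenograft 3. It had 215, 26 and 74 in the other untreated ones, and 253, 265, 0, 214 and 449 in the treated H82 xenografts 1 to 5. It had 103 and 123 UMIs in the H209 and H82 cultures, 0, 26, 1 and 15 in the untreated H209 xenografts and 0 in all 3 libraries labelled treated H209.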

How the results depend on the processing

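The fits on cells of 1 line profile, the naming of all mouse clusters by the highest score, and the fits on counts as deposited and on all cells without a mitochondrial limit were chosen after seeing the data, and the other alternatives were planned. Over 2497 values of 108 named genes and comparisons, 2365 kept direction and side of the threshold, 87 lost the call, 9 gained it, 19 reversed and 17 changed sign without a call on either side. No paired analysis was possible because replicate numbers follow accession order and nothing in the labels links a treated to an untreated sample. The counts changed most in the fits on cells of 1 line profile, which remove the mixture in the libraries labelled treated H209 but also sum fewer cells, as few as 15 to 376 per library on 1 side, and these were not told apart. With 500 cells of any profile treatment in H209 gave 9055 genes. With cells of the labelled line's profile the counts were 1003 genes for treatment in H209 and 1453 for the interaction, the correlation of effects was −0.00563, and NEUROD1 was −1.28 for H209 treatment and 1.44 for the interaction. Within tumour-like clusters alone, which leaves out the treated H209 library 3, these were 708 genes, 1225 genes, −0.0378, −1.26 and 1.42, and CLDN3 was 0.0203 for H209 treatment. With H82-like cells in every library the counts were 873 (H209 treatment), 1942 (interaction) and 3572 (line difference), and the correlation was 0.372, which was −0.0556 over genes under 2-fold apart between the cultures. There the reversed log2 values were MYC −0.26, MYCL 0.12 and MYCN −0.27 for H209 treatment, MYC 0.49, NEUROD1 0.24, MYCN 2.03 and MYCL −0.37 for the interaction, and MYC −0.14, NEUROD1 −0.42, MYCL 0.25 and PAGE5 −0.20 for the line difference. Treatment in H82 gave 2568 genes with 500 cells per library and 4274 with libraries summed by title number, which leaves fewer cells or samples. VIM lost its call in treated H82 with 500 cells, with all cells and with cells of the labelled line's profile, and kept it with H82-like cells in every library.

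For culture the count of 1074 became 2282 with DESeq2, 526 with 500 cells, 566 with all cells and no mitochondrial limit, 464 in H209 alone and 6012 in H82 alone. Leaving out single libraries gave 453 (without the untreated H82 xenograft 1) to 3311 (without the H209 culture), SOX2 ranged from −0.86 to 3.11 and VIM from −4.32 to 0.19, and VIM was 0.18 in H209 alone. The cancer testis antigen difference of 14.4 points in H209 was 5.65 without thinning, 3.66 at 4000 UMIs and 23.6 without PBK and ATAD2. It was −0.122 in H82-like cells, where the untreated share was 100%, −2.38 in H209-like cells and 6.36 in those of tumour-like clusters. Without single libraries it was 13.9 to 15.04, where the design cannot reach the threshold. In mouse macrophage-like or monocyte-like cells the count of 1 became 4 with DESeq2, 2 with no filter on low counts, 2 with untreated libraries of 6 months only, 0 with 500 cells, 0 with all ages and 0 with month as a covariate, and 0 to 6 without single libraries. The change per month gave 58 genes with DESeq2 and 0 to 2 without single libraries. With an estimated correlation 0 lists passed in each of the 8 comparisons, where 9, 15, 11, 7, 3, 6, 8 and 5 of 27 had passed. The cause was not tested except where a sentence names it. Depth limits genes near 1 count per library, and the untreated H209 xenografts 1 and 3, with 189 and 505 cells, are the thinnest human libraries.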

Other observations

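The test of an effect shared by H82-like cells under both labels was chosen after the results were seen, as were the genes named below for it.

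Further groups moved between treated and untreated H82 xenografts. Immediate early genes rose in 13 of 30 and fell in 1 (14 and 1 adjusted over the list alone; adjusted p = 0.00243, adjusted p = 0.409 with an estimated correlation), led by EGR1 (1.95 ± 0.26). Mesenchymal genes rose in 10 of 22 and fell in 0, the same adjusted over the list alone (adjusted p = 0.011, adjusted p = 0.323 with an estimated correlation), as did VIM, the intermediate filament vimentin (1.78 ± 0.39), beside the leukocyte and fibroblast markers that rose in the same libraries. VIM did not pass with 500 cells per library, with all cells or with cells of the labelled line's profile, and passed with H82-like cells in every library (1.51). Genes of S phase fell in 17 of 41 and rose in 2 (adjusted p = 0.000225, adjusted p = 0.409 with an estimated correlation), among them PRIM1, a DNA primase subunit (−0.75). Oxidative phosphorylation genes fell in 25 of 57 and rose in 0 (26 and 0 adjusted over the list alone; adjusted p = 2.05e-06, adjusted p = 0.475 with an estimated correlation), and mitochondrially encoded genes fell in 11 of 13 and rose in 0 (adjusted p = 6.2e-06, adjusted p = 0.323 with an estimated correlation), with MT-CYB at −0.88 ± 0.13. For S phase and the mitochondrially encoded genes the counts adjusted over the list alone were the same.

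H82-like cells occurred under both labels in treated and untreated libraries, so their treatment effects could be set side by side. Of 15280 genes tested in both, 443 were higher after treatment under the H209 label and 4038 in H82, and 177 were higher in both, where independent lists would share 117. Lower in both were 89 genes against 63.7, and in opposite directions 67 and 92. Genes higher in both include MYL4 (3.06 ± 0.34 under the H209 label and 2.98 ± 0.16 in H82), the myosin light chain, CAV1, the caveolar coat protein (4.11 ± 0.74 and 4.28 ± 0.52), and PYGM, muscle glycogen phosphorylase (3.29 ± 0.86 and 3.17 ± 0.28). HTRA1, a secreted serine protease, was lower in both (−1.99 ± 0.25 and −0.71 ± 0.17). Over all 15280 genes the 2 sets of effects had r = 0.372 and rho = 0.223, which were not set against splits. Over 3925 genes with at least 20 CPM that were under 2-fold apart between the cultures the 2 sets of effects had r = −0.0556 and rho = −0.0955, no farther from 0 than 2983 of 4410 splits of the libraries (exact permutation p = 0.676; most extreme other split r = −0.425). The comparison over these genes leaves a shared effect undecided, and a shared rise of MYL4, CAV1 and PYGM may be a lead worth a separate test. Whether UMIs of MYL4, CAV1 and PYGM come from tumour cells or from mouse RNA assigned to human genes was not tested.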
